A study of Mus musculus with 6 samples.

How the data were processed

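Whole genome bisulfite sequencing was carried out on small intestinal organoids, which are crypts grown in Matrigel as a self-renewing epithelium. The crypts came from C57BL/6 mice taken 7 days after a bone marrow transplant and were grown for 5 days. Recipients of BALB/c marrow formed the allogeneic group, a model of graft-versus-host disease, and recipients of C57BL/6 marrow formed the syngeneic group. Groups and replicate numbers were taken from the labels, 3 libraries per group. Per the labels' protocols, DNA was sheared to about 350 bp, converted with bisulfite and then made into libraries by adapting the single strands (IDT xGen Methyl-seq kit). The labels do not say whether the replicates of a group came from separate animals, so p-values speak of these libraries and not of mice in general.

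For each library the authors deposited counts of methylated and unmethylated calls at each CpG cytosine, for both strands, with 43845398 cytosines listed in each file. The authors also deposited a signal file per library, the mean read coverage over 1559482 intervals that were identical in the 6 libraries. The build is mm39 per the submitters' processing notes, and positions are 1-based. The aligner, the methylation caller, read filters and the choice of intervals are not given in the sources used here. Bisulfite conversion does not separate 5-methylcytosine from 5-hydroxymethylcytosine, so the methylation level is the sum of both. A C-to-T variant against the reference genome also reads as an unmethylated cytosine.

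The calls of the 2 strands of a CpG were added, which gave 21922699 CpGs, 20395559 of them on the 19 autosomes. The methylation level of a library is its methylated calls over all calls. Between 92.0% and 93.0% of the autosomal CpGs had at least 5 calls in a given library, and 89.5% had them in each of the 6. Autosomes were cut into non-overlapping 1 kb tiles. A tile was tested if at least 5 of its CpGs were covered and it held at least 20 calls in each library, which left 1590282 tiles with a median of 9 CpGs and 170 calls per library. Single CpGs were tested with at least 5 calls in each library, which left 18263936.

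Counts were tested with a logistic model per tile or CpG with the group as the term. The Pearson dispersion was moderated with limma's squeezeVar and kept at 1 or more. An F test was used, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, two-sided. For tiles the prior held 27.5 degrees of freedom at a dispersion of 1.38, more than 6 libraries can give a single tile. Each tile's dispersion was thus drawn strongly toward that shared value, and its p-value does not measure its own spread between libraries alone. Differences are allogeneic minus syngeneic, in percentage points of the mean library level. Values per library were compared by two-sided exact permutation tests, for which 3 against 3 libraries give 10 splits and a smallest p of 0.1. Tiles were classed by density as CpG-poor (under 20 CpGs), CpG-intermediate and CpG-dense (40 or more). A further division by the mean level over all 6 libraries (low under 20%, high from 80%, intermediate between) was chosen after the data were seen. By a rule fixed before the data were examined, the tiles named are the 6 with the largest increase and the 6 with the largest decrease among those past the threshold whose groups did not overlap.

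The tile test was checked on simulated calls with the depths and mean levels of the 1590282 tiles, 200 of them changed. Extra spread was drawn at random from the distribution fitted to all tiles, not from each tile's own. Called CpG-dense tiles could far exceed it, with a moderated dispersion of 20.0 at 143239001 of chromosome 5 against a fitted 1.38. Of changed tiles the test recovered 1.45% at a difference of 10 points, 57.6% at 20 points and 90.8% at 30 points. These were 1, 38 and 59 tiles beside 12 false calls, a share of false calls above the threshold of 0.05. Simulated tiles were drawn independently, so shifts shared by many tiles of a library were absent. Changed tiles and CpGs were drawn only from those well inside the intermediate range of mean level, and tiles whatever their CpG density. The rates thus do not describe tiles of low or high level, or CpG-dense tiles alone. The 12 false calls do not gauge those among CpG-dense tiles either. The test for single CpGs recovered none of the simulated differences of 20, 40 or 60 points among 18263936 CpGs, although 93.0% of those of 60 points had an unadjusted p under 0.05. Larger differences were not simulated, and depth and the number of libraries were not varied.

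Alternatives were the replicate number as a block, each library left out, other minimums of calls and CpGs, limma on the logit level with 0.5 calls added to each side, also with centred libraries, no dispersion floor, thinning to the shallowest library, a size threshold of 10 points, the X chromosome added, edgeR, Fisher's exact test on pooled calls, and tiles of 500 bp, 5 kb and 100 kb. The number of X chromosomes as a covariate and the removal of the 1% of tiles with the highest depth were chosen after the data were seen. No gene annotation of mm39 was used here, and the table of mouse genes at hand is of another build. Promoters, gene bodies, exons, introns and gene lists were therefore not analysed here, and tiles are given by position.

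Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16.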

Results

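CpG methylation was measured across the genome in intestinal organoids grown from mice that had received allogeneic or syngeneic marrow, with 3 libraries in each group. Allogeneic donor T cells attack the crypts of the recipient in this model, and the syngeneic recipients, which also received lethal irradiation, serve as the control. The allogeneic libraries held 431048803, 332015609 and 428537775 CpG calls and the syngeneic libraries 336459775, 328477049 and 403551877. Autosomal CpGs were read on average 20.3, 15.9 and 20.5 times in the allogeneic libraries and 16.1, 15.7 and 19.005 times in the syngeneic ones.

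The first comparison asked whether the genome as a whole gained or lost methylation. No clear shift was seen, though 3 against 3 libraries cannot give an exact permutation p under 0.1. The autosomal CpG level was 72.3% ± 0.934 (SD, n = 3) in allogeneic and 72.6% ± 0.325 (SD, n = 3) in syngeneic organoids, a difference of -0.321 percentage points (SE 0.571; exact permutation p = 0.7). The groups overlapped, and without allogeneic replicate 1, the library with the lowest level, the difference was 0.179. It was -0.746 without allogeneic replicate 3, -0.509 without syngeneic replicate 1 and -0.656 with the mean of per-CpG levels. Among the libraries with the depth of 1 X chromosome it was 0.269, and between the pair with the depth of 2 X chromosomes -1.50. The X chromosome was methylated at 73.7% ± 0.772 and 74.2% ± 0.888 (SD, n = 3 each; exact permutation p = 0.5). Its difference was 0.195 among the libraries with the depth of 1 X chromosome and -2.145 between the other pair.

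By class of sequence, CpG-poor tiles, which make up most of the genome, were methylated at 76.8% ± 0.989 in allogeneic and 77.4% ± 0.490 in syngeneic organoids. CpG-intermediate tiles stood at 69.6% ± 0.809 and 69.3% ± 0.765. CpG-dense tiles, which were not matched to annotated CpG islands, stood at 15.3% ± 0.968 and 14.0% ± 1.29 (SD, n = 3 for each value). The groups overlapped in each class, with exact permutation p of 0.4, 0.7 and 0.3 in this order, where 0.1 is the smallest possible. The difference in CpG-poor tiles was -0.612 points, and -0.103 without allogeneic replicate 1, -1.09 without allogeneic replicate 3 and -0.393 without syngeneic replicate 3. It was 0.116 among the libraries with the depth of 1 X chromosome and -2.07 between the other pair. That in CpG-dense tiles was 1.34 points, and 0.790 without allogeneic replicate 2, 0.606 without syngeneic replicate 3 and 0.570 with the mean of per-CpG levels. Among the libraries with the depth of 1 X chromosome the CpG-dense difference was 0.811, and between the other pair 2.41.

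**Figure D1:**
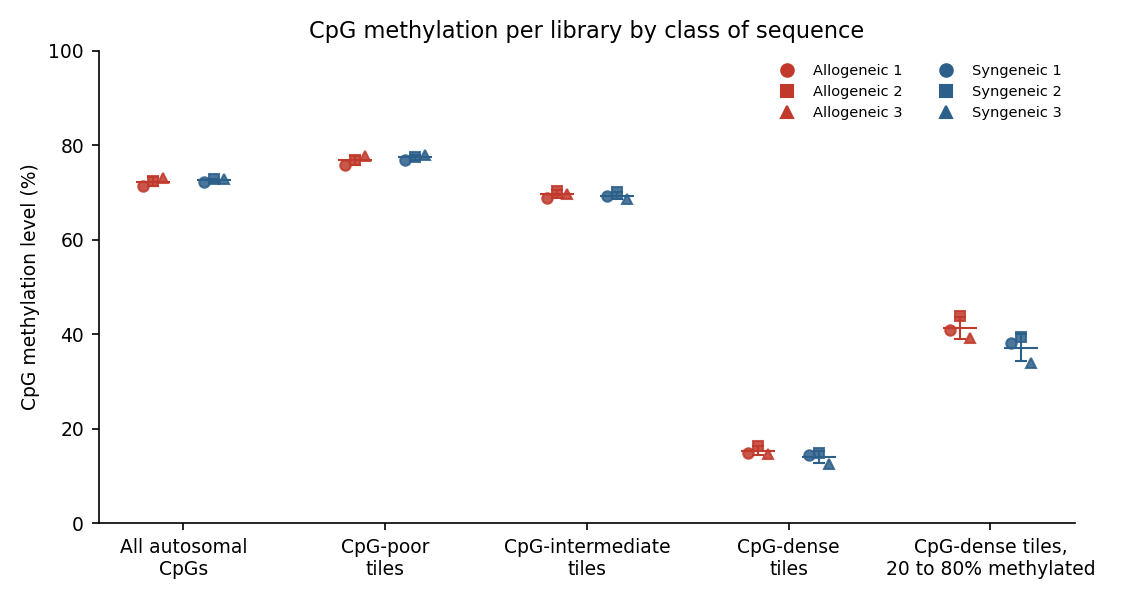
CpG methylation level in percent (vertical axis) of each library for all autosomal CpGs, for 1 kb tiles by CpG density, and for CpG-dense tiles of intermediate methylation (horizontal axis). Symbols are libraries, horizontal lines are means of 3 and bars are SD. In the rightmost class the allogeneic mean is 41.3% and the syngeneic mean 37.1%, with 1 allogeneic library below the highest syngeneic one.

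When the classes were divided further by mean level, the widest gap between groups lay in CpG-dense tiles of intermediate methylation. These 1665 tiles were methylated at 40.9%, 43.8% and 39.1% in the allogeneic and 38.2%, 39.3% and 33.9% in the syngeneic libraries. The difference was 4.13 percentage points (SE 2.12; exact permutation p = 0.2, adjusted over the 9 classes 0.75), and 78.7% of these tiles had a higher mean in the allogeneic group. CpG-dense tiles of low methylation differed by 0.361 points and those of high methylation by 0.253 points. In CpG-poor tiles of intermediate methylation the sign was opposite, with 65.7% ± 1.44 in allogeneic and 67.0% ± 1.08 in syngeneic organoids (SD, n = 3), and 36.3% of the 683310 tiles were higher in the allogeneic group (exact permutation p = 0.3). These divisions were chosen after the data were seen. Without syngeneic replicate 3, the library with the lowest CpG-dense level, the difference of 4.13 points was 2.53. It was 2.17 in tiles with at least 30 CpGs and 8.11 in those with at least 70, 2.39 with level limits of 10% and 90%, and 6.74 with calls pooled over the tiles. Among libraries with the depth of 1 X chromosome it was 2.70 points (2 allogeneic and 2 syngeneic libraries, groups overlapping), and between the pair with the depth of 2 X chromosomes it was 7.00 points. For CpG-poor tiles of intermediate methylation the difference of -1.26 points was -0.636 without allogeneic replicate 1, -2.05 without allogeneic replicate 3 and -0.677 without syngeneic replicate 3. It was -0.0482 among the libraries with the depth of 1 X chromosome and -3.70 between the other pair.

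Tests tile by tile asked where in the genome the groups differed. Of 1590282 tiles, 122 passed the threshold, 93 of them higher and 29 lower in allogeneic organoids, with a median difference of 11.7 points among the higher and -16.3 points among the lower ones. Higher tiles were CpG-rich. All of the 66 called tiles with 40 or more CpGs were higher in the allogeneic group, although that class makes up 1.33% of the tiles tested. A tile with more CpGs tends to hold more calls, so the contrast with that share does not measure enrichment. Of the 17 called CpG-poor tiles, 15 were lower. Among CpG-intermediate tiles 25 were higher and 14 lower. The called tiles lay on all 19 autosomes, with 15 on chromosome 2, 12 on chromosome 7 and 11 on chromosome 17, and 98 of them had an intermediate mean level. A difference of at least 10 points was seen in 90 of the 122. Over all tiles tested, the 3 levels of a group did not overlap those of the other in 10.1%, where chance gives 10%. With edgeR 55 tiles passed, 23 higher and 32 lower. Limma on logit levels called 1, or 0 with centred libraries, but limma on logit levels also recovered none of the 200 simulated changes. The count was 47 with the X chromosome added, 297 with the number of X chromosomes as a covariate and 0 in tiles of 5 kb. It was 189 without allogeneic replicate 1, 761 without allogeneic replicate 3, 318 and 343 without syngeneic replicates 1 and 2, and 61 without syngeneic replicate 3, of which 25 CpG-dense tiles were higher and 6 lower. Splits that mix the groups could call more tiles and be nearly as one-sided. Allogeneic replicates 1 and 2 with syngeneic replicate 2 against the rest called 354, with 137 CpG-dense tiles higher and 3 lower. With syngeneic replicate 1 in its place 439 were called, with 138 CpG-dense tiles higher and 11 lower. Allogeneic replicates 1 and 3 with syngeneic replicate 1 called 118, with 14 CpG-dense tiles higher and 21 lower.

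**Figure D2:**
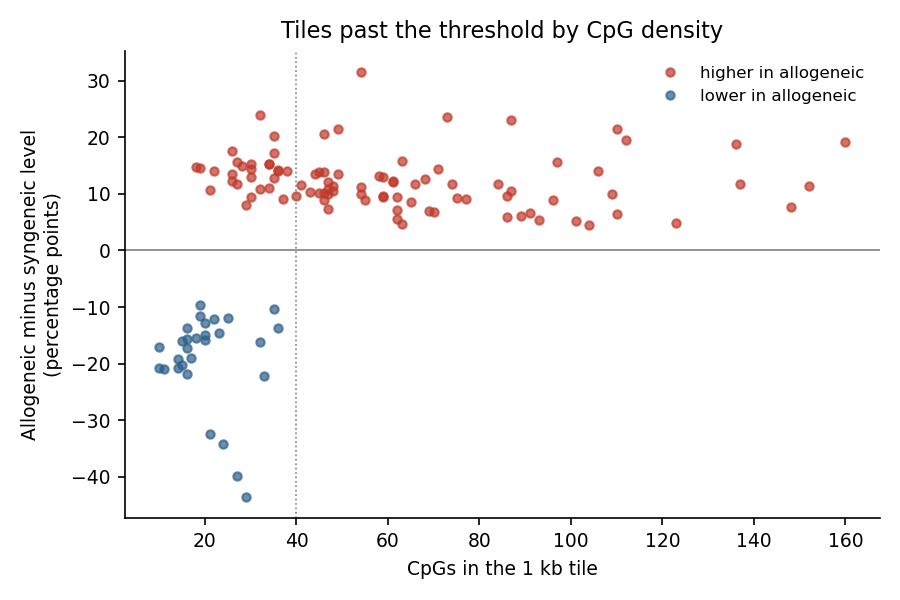
Allogeneic minus syngeneic methylation level in percentage points (vertical axis) against the number of CpGs in the tile (horizontal axis) for the 122 tiles past the threshold, each point being 1 tile. The dotted line marks 40 CpGs, and the 66 points from there on lie above 0.

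Among the tiles with the largest gain, bases 57102001 to 57103000 of chromosome 14 (54 CpGs) stood at 60.5% ± 19.3 in allogeneic and 29.0% ± 10.1 in syngeneic organoids (SD, n = 3 for this and each further tile), with a range of 56.0 points over the 6 libraries. Bases 85722001 to 85723000 of chromosome 8 (32 CpGs) had the most even libraries, at 75.8% ± 3.32 and 51.9% ± 6.15, from 419 to 658 calls per library. Both neighbouring tiles there differed by less than 1 point. On chromosome 11, bases 53354001 to 53355000 (73 CpGs) stood at 62.9% ± 4.89 and 39.4% ± 8.60. On chromosome 17, bases 35189001 to 35190000 (87 CpGs) stood at 48.5% ± 7.91 and 25.5% ± 7.497, and the tile that follows was also called, with a difference of 19.4 points. Bases 10539001 to 10540000 of the same chromosome (49 CpGs) stood at 67.3% ± 6.03 and 45.8% ± 13.1, and the difference of 21.5 points was 14.0 without syngeneic replicate 3 (adjusted p = 0.0413). On chromosome 2, bases 180284001 to 180285000 (110 CpGs) stood at 59.0% ± 10.0 and 37.5% ± 11.0.

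The tiles with the largest loss were less dense. On chromosome 17, bases 71265001 to 71266000 (29 CpGs) stood at 34.7% ± 26.0 in allogeneic and 78.2% ± 15.1 in syngeneic organoids. Bases 87350001 to 87351000 of chromosome 4 (27 CpGs) stood at 45.1% ± 27.5 and 84.9% ± 4.12, with 1 allogeneic library at 76.6%. Bases 16678001 to 16679000 of chromosome 12 (24 CpGs) stood at 61.8% ± 17.8 and 96.1% ± 3.13 and rest on 40 to 78 calls per library. Bases 35419001 to 35420000 of chromosome 17 (21 CpGs) stood at 34.4% ± 16.8 and 66.8% ± 6.87, and the tiles before and after it, neither past the threshold, differed by -14.6 and -16.6 points. On the same chromosome, bases 29614001 to 29615000 (16 CpGs) stood at 28.8% ± 4.21 and 50.6% ± 6.50. Bases 20040001 to 20041000 of chromosome 10 (11 CpGs) stood at 65.5% ± 8.79 and 86.5% ± 3.86. The range over the 6 libraries was 78.1 points at 71265001 of chromosome 17, 62.3 at 87350001 of chromosome 4 and 56.3 at 35419001 of chromosome 17. Adjusted p-values of the 12 tiles in the logistic test ran from 5.72e-05 on chromosomes 8 and 11 to 0.0343 on chromosome 12. Their dispersions were drawn toward the value shared by all tiles. Between libraries, the difference of -43.5 points at 71265001 of chromosome 17 had an SE of 17.4. That of 24.0 points at 85722001 of chromosome 8 had an SE of 4.04. Limma on logit levels called none of the 12, but it also recovered none of the simulated changes of 10, 20 or 30 points. The tiles named on chromosomes 2, 12 and 14 fell short of the threshold when the X chromosome was added. Without syngeneic replicate 3 the same tiles and those at 29614001 and 35419001 of chromosome 17 fell short, with differences of 15.1, -33.3, 25.8, -18.4 and -30.8 points. The tiles on chromosomes 2 and 14 also fell short without allogeneic replicate 1 (21.3 and 25.0 points) or 2 (16.5 and 27.0 points), and that on chromosome 10 without allogeneic replicate 1 (-18.99 points). The tile on chromosome 12 also fell short without allogeneic replicate 3 (-25.1 points) or syngeneic replicate 2 (-33.4 points).

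**Figure D3:**
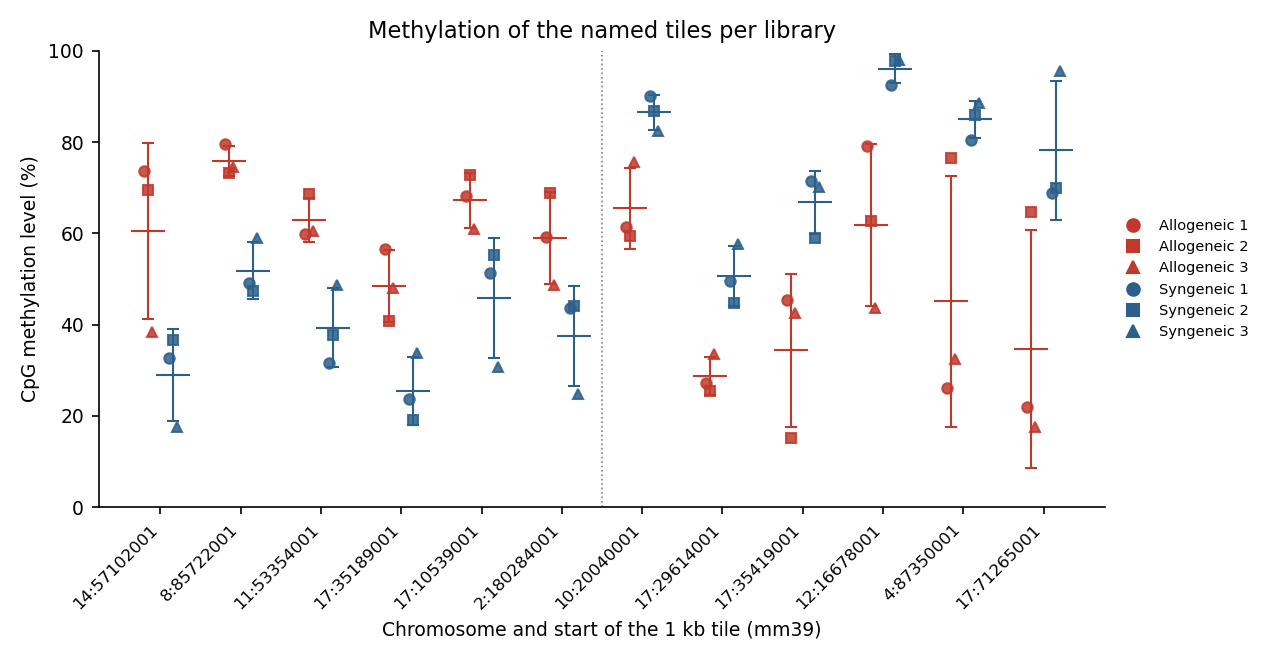
CpG methylation level in percent (vertical axis) of each library in the 12 named tiles (horizontal axis, chromosome and first base). Symbols are libraries, horizontal lines are means of 3 and bars are SD. The dotted line parts the 6 tiles with the largest gain from the 6 with the largest loss, whose means run from 28.8% to 65.5% in the allogeneic group.

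At single CpGs the moderated logistic test (limma's squeezeVar) called 0 of 18263936, with 387651 at an unadjusted p under 0.05. Limma on logit levels also called 0, with 927051 at an unadjusted p under 0.05. Simulated differences of 20, 40 and 60 points at single CpGs were not recovered either, and larger ones were not simulated.

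Depth by chromosome showed how the libraries differ apart from their group. Calls per CpG on the X chromosome relative to the autosomes were 0.760 in allogeneic replicate 1 and 0.7499 in syngeneic replicate 3, and 0.386 to 0.404 in the other libraries. On the Y chromosome the same ratio was 0.00667 and 0.00248 in those libraries and 0.0504 to 0.0556 in the rest. Each group thus held 1 library with the depth of 2 X chromosomes and no Y chromosome, and 2 libraries with 1 X chromosome and a Y chromosome. The labels used here do not give the sex of the mice.

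The mitochondrial genome was covered 145 ± 19.03 times as deeply as the autosomes in allogeneic and 168 ± 43.0 times in syngeneic organoids (SD, n = 3; exact permutation p = 0.5). The difference of -22.5 was -13.2 without allogeneic replicate 1, -45.4 without syngeneic replicate 1 and -2.73 without syngeneic replicate 2. Its 287 CpGs, a gauge of incomplete conversion, were called methylated at 2.25% ± 0.00931 in allogeneic and 2.40% ± 0.0914 in syngeneic libraries. All 3 allogeneic values lay below the 3 syngeneic ones, with a difference of -0.149 percentage points (SE 0.0530; exact permutation p = 0.1, the smallest this design can give), and of -0.0973 without syngeneic replicate 3.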

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

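Settings named as added were chosen after the data were seen. All exact tests of levels had p of 0.1 or more under each alternative, which 3 against 3 libraries cannot pass. Of 79 alternative values of the levels, 75 kept their sign. Values with the replicate block equal the main ones by construction, and thinning cannot shift an expected level, so their signs were fixed. Differences by the number of X chromosomes are not among the 79. With each library left out in turn, the genome-wide difference ran from -0.746 to 0.179 points and turned without allogeneic replicate 1. That of CpG-intermediate tiles ran from -0.102 to 0.703, turned without allogeneic replicate 2 or syngeneic replicate 3, and was -0.0240 with the mean of per-CpG levels. The difference in CpG-dense tiles of intermediate methylation ran from 2.17 to 8.11 points over 16 alternatives (all added).

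The count of 122 tiles ran from 61 (without syngeneic replicate 3) to 761 (without allogeneic replicate 3) when a library was left out. It was 55 with edgeR, 1 with limma on logit levels and 0 with centred libraries and limma. On simulated tiles limma recovered none of the 200 changes. Fisher's exact test on pooled calls, which ignores the spread between libraries, called 10819, and 4531 tiles without a change in the simulation. The count was 227 with a minimum of 3 covered CpGs, 47 with the X chromosome added, 297 with the number of X chromosomes as a covariate (added), 0 in tiles of 5 kb and 9 in tiles of 100 kb; the cause was not tested. A lower or higher minimum of calls, no dispersion floor, thinning, 500 bp tiles, the size threshold and removal of the deepest tiles (added) gave 90 to 180. The 1 tile called by limma, named after its values were seen, was bases 3230001 to 3231000 of chromosome 5 (94.2% in allogeneic, 100% in syngeneic organoids) and was not among the 122. For the 12 named tiles, 201 of 240 alternative values stayed past the threshold. Not all of the 240 could fall short. Each named tile differed by more than the size threshold, and leaving out the dispersion floor left their adjusted p-values unchanged. Other minimums of calls or CpGs used the same calls in these tiles, and Fisher's exact test ignores the spread between libraries. The 201 values thus overstate how well the named tiles hold. Single CpGs gave 0 calls under each alternative.

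With the replicate number as a block (replicate block) 1658 tiles were called, 1116 higher and 542 lower, among them all 122. The labels give no shared animal or batch for a number. Deviations of same-numbered libraries from their group means correlated at 0.0157, 0.0375 and 0.0626 over tiles, under the 0.1 set for pairing, though each library correlated best with its own number, which is a hint from the data and not the design. The block changed no other call. Promoters, gene bodies and gene lists were not run. The tile test recovered 57.6% of simulated differences of 20 points and 1.45% of those of 10 points, all placed in tiles of intermediate level.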

Other observations

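The tests of conversion, of depth and of copy number below were chosen after the result was seen, as were the correlations, the X chromosome classes, the depth windows, the 100 kb windows without 1 library and the lists of variable tiles and lost CpGs. On the X chromosome the level of CpG-dense tiles went mainly with the number of X chromosomes. These 734 tiles were methylated at 58.3% in allogeneic replicate 1 and 54.4% in syngeneic replicate 3, the libraries with the depth of 2 X chromosomes, and at 37.6% to 39.5% in the other 4. Of those 4, the allogeneic libraries stood at 39.45% and 37.71% and the syngeneic ones at 37.60% and 37.70%. At each number of X chromosomes the allogeneic libraries were thus the higher ones, in part by very little. Over all libraries the groups overlapped (exact permutation p = 0.5). Methylation of CpG islands on the inactive X chromosome is textbook knowledge. CpG-poor tiles of the X chromosome ran from 75.2% to 78.2%, with allogeneic replicate 1 lowest.

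Some tiles differed widely between libraries, and as a set they did not follow the groups. A range of at least 50 points over the 6 libraries, each with at least 50 calls, was found in 68 of 1547210 tiles, of which 18 were CpG-dense, 28 CpG-intermediate and 22 CpG-poor. The groups did not overlap in 7 of the 68, or 10.3%, where chance gives 10%. Of the named tiles, those at 57102001 of chromosome 14, 87350001 of chromosome 4 and 71265001 and 35419001 of chromosome 17 are among the 7, so a set that separates at the chance rate holds the named tile with the largest gain and the pair with the largest losses. The widest range was at bases 164052001 to 164053000 of chromosome 1 (64 CpGs), with 96.5%, 61.0% and 90.9% in allogeneic and 79.8%, 83.6% and 6.25% in syngeneic libraries. At bases 5956001 to 5960000 of chromosome 11, 4 successive tiles stood at 3.46% to 6.90% in syngeneic replicate 3 alone.

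In 27 of 23856 windows of 100 kb the depth of at least 1 library lay 0.5 or more on the log2 scale from the median of the 6, and these windows formed 14 regions. Bases 66000001 to 66700000 of chromosome 13 stood at -2.16 in syngeneic replicate 3, at -0.44 and -0.31 in allogeneic replicate 2 and syngeneic replicate 2, and at 0.26 to 0.32 in the other libraries. Bases 15600001 to 15900000 of chromosome 5 stood at -1.23 in allogeneic replicate 3. CpGs at under 10% in 1 library and at 80% or more in the other 5 numbered 60 in syngeneic replicate 3, 13 in allogeneic replicate 3 and at most 1 elsewhere, among 15184529 CpGs with at least 10 calls in each library. No CpG had that contrast between the groups.

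The higher mean level of CpG-dense tiles of intermediate methylation in allogeneic libraries passed no test (exact permutation p = 0.2, adjusted 0.75) and was 2.53 points without syngeneic replicate 3. Incomplete conversion would raise nearly unmethylated sequence too, but the mitochondrial level differed by -0.149 points, below the rise of 1 point set for that explanation. The number of calls as such cannot shift an expected share of calls, so thinning, which left the difference at 4.13 points, tested nothing further. Whether libraries of unequal depth differ in other ways that bear on the difference was not tested. A loss of unmethylated molecules would need calls in CpG-dense tiles of low relative to high methylation to stand at 0.841 of the syngeneic ratio. They stood at 0.960 (SE 0.0411), above the needed value by the margin set beforehand. An SE from 3 libraries per group is too uncertain for that margin to exclude the explanation. The groups overlapped in the ratio (exact permutation p = 0.6), and a loss of unmethylated molecules stays open. The share of calls in CpG-dense tiles was 5.92% ± 0.0204 in allogeneic and 6.22% ± 0.191 in syngeneic libraries (SD, n = 3; exact permutation p = 0.1, the smallest possible), and a biological effect of the graft was not tested apart from it.

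Over the 6 libraries that share went against the level of these tiles (Pearson r = -0.88, exact permutation p = 0.0139; Spearman rho = -0.83, exact permutation p = 0.0583). Without the libraries farthest from the median share, syngeneic replicates 2 and 3, r was -0.78. The ratio of low to high calls gave r = -0.93 (exact permutation p = 0.0278; rho = -0.71, exact permutation p = 0.136), and r was 0.11 without allogeneic replicate 2 and syngeneic replicate 3, so that relation rests on those libraries. The level of CpG-poor tiles of intermediate methylation gave r = -0.78 (exact permutation p = 0.0694; rho = -0.77, exact permutation p = 0.103) and -0.66 without allogeneic replicate 1 and syngeneic replicate 3. Adjusted over these 3 relations, the p-values of r were 0.0417, 0.0417 and 0.0694. Centred on the group means, with exact permutation inside the groups (36 arrangements, smallest p 0.0278), the share gave r = -0.75 (p = 0.111), the ratio r = -0.97 (p = 0.0278) and the CpG-poor level r = -0.68 (p = 0.222), with adjusted p of 0.167, 0.0833 and 0.222.

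For the 122 called tiles, 4 of the 10 splits of the 6 libraries, the real one included, gave at least as many, and the highest other split gave 439. With 10 splits no share under 0.05 can be reached. That split set allogeneic replicates 1 and 2 and syngeneic replicate 1 against the rest, and a count so far above the real one points to a structure among the libraries other than their group. Of the tiles it called, 138 CpG-dense ones were higher and 11 lower. For single CpGs all 10 splits gave 0 calls.

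Of the 9 called windows of 100 kb, 8 were higher in allogeneic libraries and 1 was lower. Syngeneic replicate 3 was the lowest library in all 8 higher ones, and the groups overlapped in 3 of them. At bases 40100001 to 40200000 of chromosome 17 the difference of 10.04 points was 3.70 without that library. At this window size the moderation gave all windows the same dispersion. Adjusted p-values of these windows thus do not measure the spread of a single window between libraries.

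The lower window, bases 26500001 to 26600000 of chromosome 7, stood at 74.4% ± 2.10 in allogeneic and 80.02% ± 1.33 in syngeneic organoids (SD, n = 3). Its adjusted p in the logistic test was 0.0478, from the dispersion common to all windows. Its depth was lower in all 3 allogeneic libraries, by a mean of -0.73 on the log2 scale, with allogeneic replicate 3 lowest. A copy number difference between the mice is a candidate explanation, and it goes with this depth, while an effect of the graft on the window was not tested apart from it.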
